A study of Mus musculus with 3 samples.

How the data were processed

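Liver RNA of female C57BL/6 mice was measured on 3 microarrays with 2 channels each. Per the labels' protocols, mice received 3 ng lipopolysaccharide (LPS, a bacterial cell wall component) with 10 mg D-galactosamine (GalN) by intraperitoneal injection, and liver was taken 24 h later. Total RNA was extracted with a miRNeasy kit, amplified as amino allyl RNA, coupled to dyes and processed by a Toray protocol, per the labels' protocols. On every array the Cy5 channel held liver RNA of untreated wild-type mice, which served as the common reference. The Cy3 channel held wild-type liver after LPS/GalN on the first array, untreated TMX-null liver on the second, and TMX-null liver after LPS/GalN on the third. The labels do not say whether 1 mouse or a pool stands behind each channel, nor whether the reference RNA was one preparation. Each group has 1 array, no dyes were exchanged, and the reference was the control's own RNA, so its ratio against 0 leaves out the spread of the control.

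The authors deposited 1 table of log ratios, read here on the log2 scale. The logarithm's base, the numerator of the ratio, the image analysis, the background correction, the normalization and the rule behind blank cells are not given in the sources used here. The values were signed and ran from -6.40 to 8.04, which excludes a decimal logarithm as a measure of RNA, since 8.04 would be that many powers of 10. A natural logarithm is not excluded, and every fold given here would then be raised to the power 1.44. The median over all deposited log2 values was -7.06e-06, -6.94e-05 and 1.14e-04 on the wild-type LPS/GalN, the TMX-null untreated and the TMX-null LPS/GalN array, so each array had been centred before deposit. Their SDs of 0.60, 0.52 and 1.05 show that spreads had not been made equal.

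Of 23473 table rows, 16890, 15446 and 16187 held a value on these 3 arrays, 13674 held one on all 3, and 4639 were blank throughout. GEO's platform annotation gave 1 symbol to 16631 rows, several to 0, and none to 6842, which are unnamed here. Symbols were updated through the synonyms of the mouse RefSeq table of assembly GRCm38.p6: 12622 rows had a current symbol, 3947 were renamed and 62 kept the annotation's name. That table served for names and gene order alone, and no coordinates are given. The measurement was taken over the 10179 named genes with a value on all 3 arrays. Probes of a gene were averaged (86 genes had several), and each array was then centred on its median over these genes, which was -0.05, -0.03 and -0.07.

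There are no signal or background values in the table, so dim genes cannot be told from bright ones, and the number of arrays limits the precision. Differences between probes of the same gene give the only measure of error. Over 81 genes with 2 probes, the SD of a single probe was 0.42, 0.42 and 0.76 log2 on the 3 arrays, and 0.67 for the difference between the TMX-null arrays. It includes real differences between transcripts and leaves out differences between mice. Across these genes the 2 probes correlated with r = 0.31, 0.17 and 0.44 on the 3 arrays.

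The direction of the ratio was to be called only if Tmx1, the gene of the TMX protein, and the median of an acute phase list pointed the same way. Tmx1 pointed to sample over reference, and the acute phase medians did not settle the matter, since they were 0.03 in treated wild-type and -0.87 in treated TMX-null liver, with members on both sides. By the rule as fixed, no direction would be given. A further test was therefore chosen after the data were seen. A row with a value on a single array was expected to owe it to that array's own sample, if the same reference RNA was used on all. Of such rows, 1072 of 1281 (83.7%), 556 of 610 (91.1%) and 797 of 928 (85.9%) were positive on the 3 arrays, against 44.7%, 46.4% and 45.6% of the rows with a value on all 3. These rows cannot decide the direction, since the rule behind blank cells is unknown and no dyes were exchanged. A dye effect on such rows could make them positive whichever channel was the numerator. The share was also highest in untreated TMX-null liver, the array with the smallest spread. Sample over reference is taken as the likely direction on the basis of Tmx1 alone. If the ratio ran the other way, every "higher" would read "lower".

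Comparisons were fixed before the data were examined. The 3 arrays give each liver against untreated wild-type liver. Differences between arrays give treated against untreated TMX-null liver, treated TMX-null against treated wild-type liver, and the difference of the responses in the 2 genotypes. In the first 2 of these differences the reference and the dye effect of a gene cancel, and in the third each of them enters once. That, and every later statement that the reference cancels or is shared, assumes the same preparation of reference RNA on all arrays. With 1 array per group no test was possible and no p-value is given. Genes are counted as different at 2-fold, a log2 ratio of 1 either way. There were 40 fixed gene lists, 26 of pathways and 14 of cell type or sex markers, with 877 entries, of which 643 were measured on all 3 arrays. For each list the median log2 ratio is given with its percentile among 10000 random lists of the same size. A median outside the central 95% of these is called outside the random range. Random lists were not matched on signal, which the table does not give. These percentiles describe the arrays, not the conditions.

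Named genes followed a fixed rule. Pseudocode: for each comparison take the 8 highest and 8 lowest genes (6 and 6 for the difference of responses), then Tmx1 on every array, then the 2 highest and 2 lowest members of each list. Genes whose probes differed in sign by over 1 and predicted genes were passed over in the ranks. Alternatives covered thresholds of 1.5-fold and 3-fold, the centring, equal spread across arrays, genes measured on the comparison's own arrays, other treatments of probes, unnamed rows, list means, 2000 random lists matched on the size of the ratio in untreated TMX-null liver, the sign and the logarithm's base. Use of the untreated TMX-null array in place of the reference for treated wild-type liver was added after the data were seen. In comparisons that include the untreated TMX-null array, matching on its ratios conditions on the values compared, so matched percentiles are given for the treated livers against the reference alone.

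Correlations across genes are given with the value from simulated unchanged livers set against a shared reference. The code was tested on simulated data with 200 genes shifted on the TMX-null LPS/GalN array and noise with an SD of 0.30 log2, less than the SD of a single probe on any of the arrays. In that array's comparison with untreated wild-type liver over 10179 genes, 92.0% of the 100 genes shifted by 1.5 log2 and 100.0% of the 100 shifted by 3 passed 2-fold, as did 0.23% of the 9979 others. In the comparison of the treated livers these shares were 87.0%, 100.0% and 2.01%. Of 300 simulated lists in the comparison of untreated livers, 5.67% lay outside the random range with no shift. With a shift of 0.5 log2, 99.3% were found. The first share was fixed in advance, since these lists were drawn at random from the same values as the random lists. All held more genes than the smallest marker lists, and genes that vary together were not simulated. These shares are therefore not error rates of the lists reported here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.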

Results

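Gene expression was compared between livers of wild-type mice and of mice lacking TMX, a thioredoxin-related transmembrane protein of the endoplasmic reticulum, with and without LPS/GalN. D-galactosamine depletes hepatocytes of uridine nucleotides and sensitises the liver to LPS, and the combination is a common model of acute inflammatory liver injury. The design held 3 arrays, with 1 each for wild-type LPS/GalN, TMX-null untreated and TMX-null LPS/GalN liver, all set against untreated wild-type liver. All values are log2 ratios of the authors' deposited table, centred per array over 10179 genes. There were no replicates, so no difference below was tested against the variation between mice. Values describe these arrays, and the SD of a single probe (0.42, 0.42 and 0.76 log2 on the 3 arrays) is the only error at hand.

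Tmx1, the targeted gene, was the lowest of all 10179 genes in untreated TMX-null liver, at -2.96, which is 7.78-fold below untreated wild-type liver. It stood at -3.88 in TMX-null liver after LPS/GalN (14.7-fold lower, rank 23 from the lowest) and at 0.59 in treated wild-type liver. Neither the part of the gene that was deleted nor the place of the probe is given in the sources used here. These signs rest on reading the deposited values as sample over reference. That direction is likely, but the labels do not state it. The acute phase list, which was to serve as a second check, did not settle it, with medians of 0.03 and -0.87 after LPS/GalN in wild-type and TMX-null liver. The share of positive values among rows measured on a single array, 83.7% to 91.1%, was examined in its place. It cannot decide the direction either, since a dye effect could give it too, so the direction rests on Tmx1. With the opposite numerator, every direction below turns.

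Treated TMX-null liver differed most from the reference. At 2-fold, 2727 genes differed there (1381 higher and 1346 lower), against 463 in treated wild-type liver (285 higher and 178 lower) and 266 in untreated TMX-null liver (181 higher and 85 lower). The SD over genes was 1.04, 0.48 and 0.40 log2, in the same order, and in untreated TMX-null liver it did not exceed that of a single probe (0.42). These counts depend on the unequal spread of the arrays, since scaling all arrays to the same spread gave 1090, 1029 and 1016 genes. They also depend on the genes taken, since all genes with a value on the array in question gave 3279 (1716 higher), 998 (765 higher) and 640 (536 higher).

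**Figure D1:**
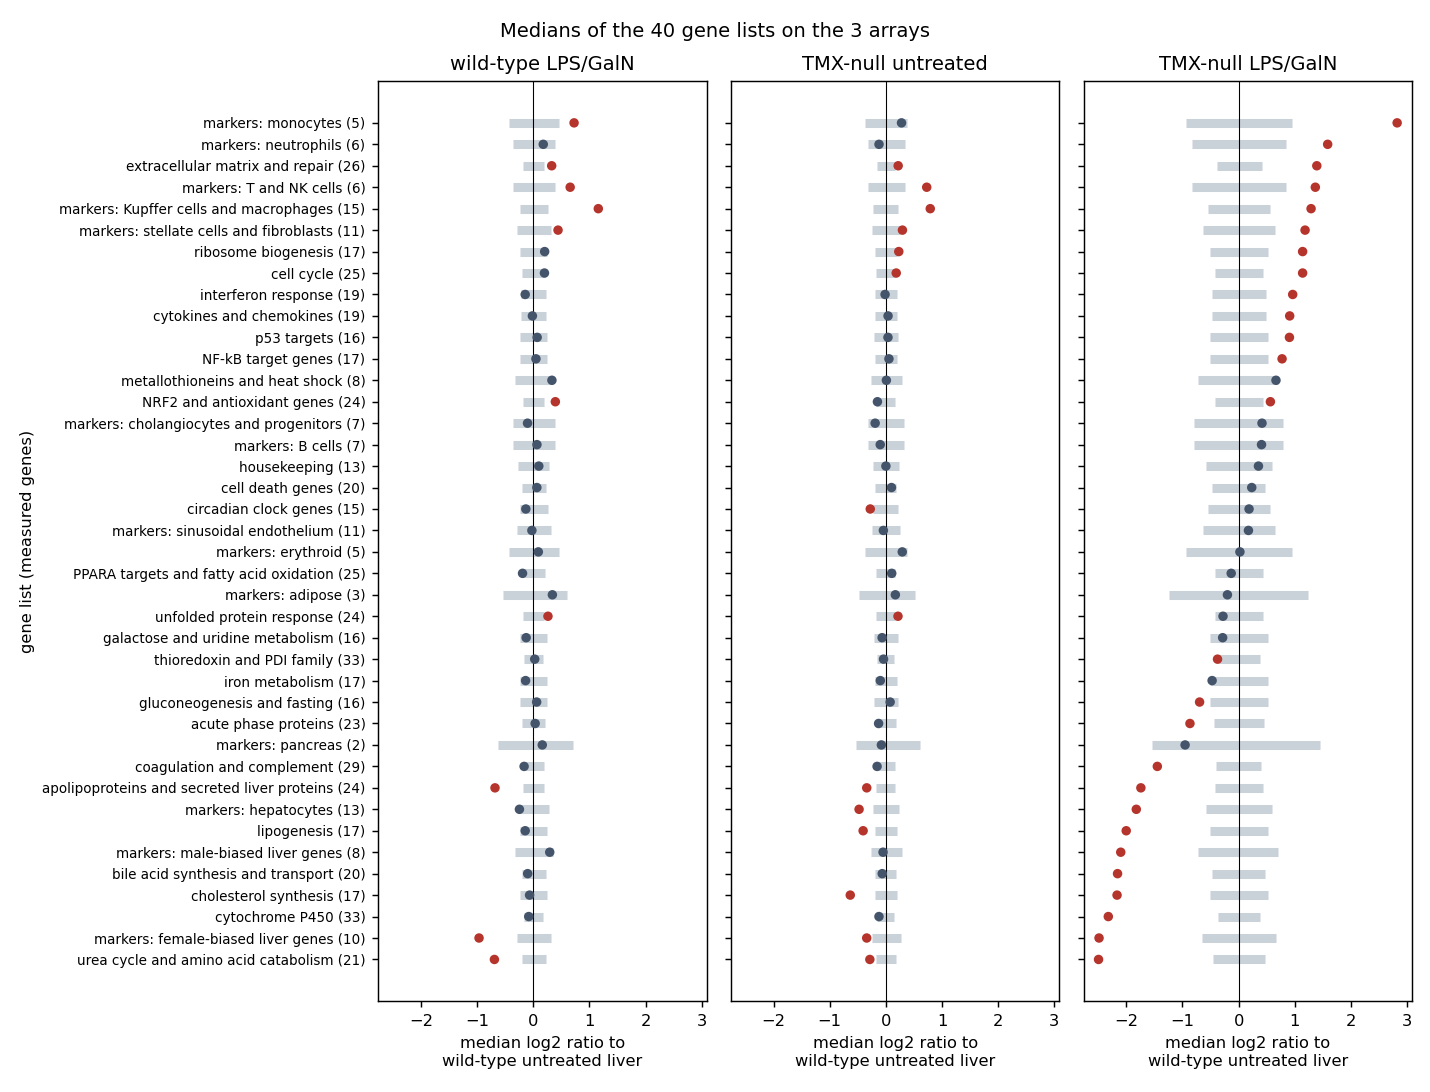
Medians of the 40 gene lists on the 3 arrays, as log2 ratio to untreated wild-type liver (x axis, per panel), with the number of measured genes in brackets. Grey bars span the central 95% of the medians of 10000 random lists of that size, and red points lie outside. The monocyte list reached 2.82 and the urea cycle and amino acid list -2.49 in treated TMX-null liver.

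The first comparison asked how the wild-type liver differed after LPS/GalN. Genes of macrophages and antioxidant defence lay high, and secreted liver proteins, amino acid catabolism and female-biased genes lay low. Saa3, an inducible serum amyloid A, had the highest ratio at 4.22. Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 3.18 and Marco, a scavenger receptor of macrophages, at 3.13. Egr1, an immediate early transcription factor, stood at 2.68 and the acute phase protein gene Orm2 at 2.38. Tcte3 (2.34), the thyroxine carrier gene Serpina7 (2.30) and Ear6 (2.08), an eosinophil-type ribonuclease, completed the 8 highest. Hamp (-3.99) and Hamp2 (-3.80), which encode the iron hormone hepcidin and a close copy of it whose probes may not separate them, were the lowest. They were followed by B3gnt4 (-3.11), the acyl-CoA thioesterase gene Acot3 (-2.99), Krtap4-2 (-2.94), Gpcpd1 (-2.73), the steroid hydroxylase gene Cyp17a1 (-2.58) and Cyp8b1 (-2.44), an enzyme of bile acid synthesis.

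Among the lists, 7 medians lay above and 3 below the random range in treated wild-type liver, where chance gives 1 on each side. With list means in place of medians 19 lists lay outside. Macrophage markers had a median of 1.16, with 10 of 15 genes at least 2-fold higher, among them Marco and Vsig4 (1.81). The other high medians were those of monocyte markers (0.73, 0 of 5 at 2-fold), T and NK cell markers (0.66, with Ccl5 at 2.08 and Nkg7 at 1.60), stellate cell markers (0.44), NRF2 and antioxidant genes (0.39, with Gsta2 at 1.98), extracellular matrix genes (0.33, with Lum at 1.23) and unfolded protein response genes (0.26, with Creld2 at 1.42). Of the 10 lists outside the random range, T and NK cell markers alone fell inside the range (percentile 94.2) when random lists were matched on the size of the ratio in untreated TMX-null liver. The median of the urea cycle and amino acid list was -0.69, with Oat at -1.83 and Hpd at -1.38, while Glul, glutamine synthetase, stood at 1.15. Apolipoproteins and secreted liver proteins had a median of -0.68, with 7 of 24 genes 2-fold lower, including Apoa2 (-2.17) and Serpina6 (-1.91). Female-biased liver genes had a median of -0.96, with 5 of 10 genes 2-fold lower. Male-biased genes stood at 0.29, inside the random range (percentile 95.4), with 6 of 8 above 0 and Hsd3b5 the highest at 2.04. Hepatocyte markers as a whole were inside the random range at -0.25. So were cytochrome P450 genes at -0.08, although Cyp2e1 stood at -1.54, and cytokines and chemokines at -0.01. The acute phase list stood at 0.03, with 5 of 23 genes 2-fold higher and 1 lower.

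Many of these ratios were smaller against another untreated liver. When treated wild-type liver was instead set against untreated TMX-null liver, a comparison added after the data were seen in which reference and dyes cancel but genotype differs, 256 of the 285 higher genes and 177 of the 178 lower genes kept their sign. The treated array's values chose these genes and enter this difference too, so most signs were likely to be kept. At 2-fold, 67 of the 285 and 83 of the 178 remained. A fall was likely as well, since these genes were chosen for large ratios to the reference. Over all genes, 212 were 2-fold higher and 202 lower in this comparison, 414 in all, against 463 with the reference. Egr1 stood at 3.11, Cdkn1a at 2.99, Marco at 2.04, Hamp at -2.72 and Cyp8b1 at -2.26 in that comparison, and Ear6 at 0.46. Of the 10 lists outside the random range, 6 stayed outside, with medians of 0.37 for macrophage markers, 0.30 for NRF2 and antioxidant genes, 0.20 for the unfolded protein response, -0.30 for urea cycle and amino acid genes, -0.32 for secreted liver proteins and -0.77 for female-biased genes. Extracellular matrix genes (0.10, percentile 87.4), monocyte markers (0.15), stellate cell markers (0.09) and T and NK cell markers (-0.18) lay inside it. A further 8 lists lay outside it here alone. Among them were cholesterol synthesis (0.60), lipogenesis (0.38) and clock genes (0.31), all of which lay low in untreated TMX-null liver. The acute phase list was another at 0.22, but it stood at 0.03 against the reference and at -0.13 in untreated TMX-null liver.

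The comparison of untreated livers set TMX-null against wild-type liver without LPS/GalN, on 1 array that cannot separate the deletion from other differences between the mice. Genes of cholesterol and fatty acid synthesis lay low together while macrophage markers lay high. The cholesterol synthesis list had a median of -0.63, below all 10000 random lists, with 16 of 17 genes below 0. Mvd (-1.24), an enzyme of the mevalonate pathway, and Dhcr7 (-1.05), which catalyses the last step, were the lowest, and Tm7sf2 (0.03) was the exception. The same list stood at -0.06 in treated wild-type liver. Lipogenesis genes had a median of -0.41, with Acss2 at -0.88 and Thrsp at -0.83 and none at 2-fold. Hepatocyte markers stood at -0.48, secreted liver proteins at -0.34 with Apoa2 at -1.42, female-biased genes at -0.34, urea cycle and amino acid genes at -0.29, and clock genes at -0.28. Cytochrome P450 genes (-0.12) and bile acid genes (-0.07) were inside the random range, and so was the list of the thioredoxin and protein disulfide isomerase family (-0.04), where Txnip stood at 1.03. Tmx1 belongs to this family but was not a member of the list, whose lowest gene stood at -0.52.

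Macrophage markers had a median of 0.79 in untreated TMX-null liver, with 4 of 15 genes 2-fold higher, led by Vsig4 (1.30) and Cd5l (1.25). T and NK cell markers stood at 0.73, with Nkg7, a granule protein of cytotoxic lymphocytes, at 2.21, while B cell markers were inside the random range at -0.10. The unfolded protein response list stood at 0.21, stellate cell markers at 0.29, extracellular matrix genes at 0.22, ribosome biogenesis genes at 0.23 and cell cycle genes at 0.18, and all of these were above the random range. The highest single genes were Milr1 (2.56), Tex37 (2.26), Nkg7, the T cell kinase gene Txk (2.16), Olfr107 (2.10), Cst6 (2.08), Sntn (1.97) and Sema7a (1.89). The lowest after Tmx1 were Cryba2 (-1.75), Tcl1 (-1.53), Rgs9 (-1.51), Cdx4 (-1.50), Dmkn (-1.48), Nudcd3 (-1.47) and Ltbp3 (-1.47). Several of these, such as Olfr107, Cryba2 and Cdx4, are genes of other tissues, and no signal was at hand to tell whether they were above background. Of the 181 genes higher here, 70 were also higher in treated wild-type liver, where a shared reference alone gave 40.5 in simulation and independent lists 5.07. Of the 85 lower, 7 were also lower there, where these gave 17.3 and 1.49. The simulation assumed a reference that varied as much as the livers and no noise, so it does not measure how much the real reference contributed.

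Treated TMX-null liver, set against untreated wild-type liver, had low medians for many lists of hepatocyte functions and high medians for chemokines, myeloid cells, matrix and cell growth. PPARA targets and fatty acid oxidation (-0.13), galactose and uridine genes (-0.28) and iron genes (-0.47) lay inside the random range. The highest genes were Ccl2 (5.81), the chemokine that recruits monocytes, S100a4 (5.45), Ly6d (5.38), Tnfrsf12a (4.94), which encodes the TWEAK receptor, S100a9 (4.45), a neutrophil and monocyte protein, Ier3 (4.40), Cdkn1a (4.33) and Marco (4.10). Of these, Cdkn1a, Marco and S100a9 (1.80) were also at least 2-fold higher in treated wild-type liver, but Ccl2 stood there at -0.01. The lowest genes were Upp2 (-6.33), the liver uridine phosphorylase, Inmt (-5.39), Thrsp (-5.29), a regulator of lipogenesis, the clock output gene Dbp (-5.25), Serpina6 (-5.15), which encodes corticosteroid-binding globulin, Car3 (-4.86), Hsd3b3 (-4.78) and Hsd3b6 (-4.72). The Hsd3b genes are near-identical copies, and their probes may not separate them.

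In this liver 13 list medians lay above and 13 below the random range. Cytochrome P450 genes had a median of -2.32, with 25 of 33 at least 2-fold lower and none higher, including Cyp2e1 (-4.47) and Cyp1a2 (-3.46). Bile acid synthesis and transport stood at -2.15 (16 of 20 lower), with Akr1d1 at -4.42 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -4.22. Urea cycle and amino acid genes stood at -2.49 (19 of 21 lower), cholesterol synthesis at -2.16 (14 of 17), lipogenesis at -2.00 (15 of 17), and coagulation and complement at -1.45 (25 of 29), with F10 at -2.79 and F7 at -2.55. Female-biased genes (-2.48) and male-biased genes (-2.10) were both low. Hepatocyte markers lay low beside all of these, at -1.82, and ranged from Cyp2e1 to Apob (-0.14). Secreted liver proteins stood at -1.74, but 2 of their 24 genes, Apoa4 (2.40) and Apoc2 (1.41), were higher. Gluconeogenesis and fasting genes stood at -0.69, with Igfbp1 at 3.15, and the thioredoxin family at -0.38.

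The acute phase list had a median of -0.87, with 9 of 23 genes 2-fold lower, among them Saa4 (-2.93) and Fgg (-1.87), and 5 higher, among them Cd14 (3.46) and Lcn2 (2.28). Of the inflammatory lists, interferon response genes stood at 0.96 (9 of 19 higher, with Oas1a at 3.40 and Rsad2 at 3.05), cytokines and chemokines at 0.91 (8 of 19, with Ccl6 at 3.84) and NF-kB targets at 0.77 (7 of 17, with Vcam1 at 3.24). Monocyte markers stood at 2.82 (5 of 5 higher), macrophage markers at 1.29 (10 of 15) and T and NK cell markers at 1.36, the only one of the 26 lists inside the range with matched random lists (percentile 97.35). Neutrophil markers stood at 1.58 but were split, with S100a9 at 4.45 and Ly6g at -2.50. Extracellular matrix genes stood at 1.39 (18 of 26 higher, with Lgals3 at 3.86), stellate cell markers at 1.18 (with Acta2 at 3.31), cell cycle genes at 1.14 (14 of 25, with Mcm6 at 2.71), ribosome biogenesis at 1.14 (11 of 17, with Nhp2 at 2.74) and p53 targets at 0.90 (7 of 16, with Phlda3 at 3.38). NRF2 genes stood at 0.57 with members on both sides, from Hmox1 (3.31) to Gsta3 (-3.26). B cell markers (0.41), sinusoidal endothelium markers (0.17), cell death genes (0.23) and housekeeping genes (0.35) lay inside the random range. Among the housekeeping genes Actb stood at 2.02 and B2m at -1.12.

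**Figure D2:**
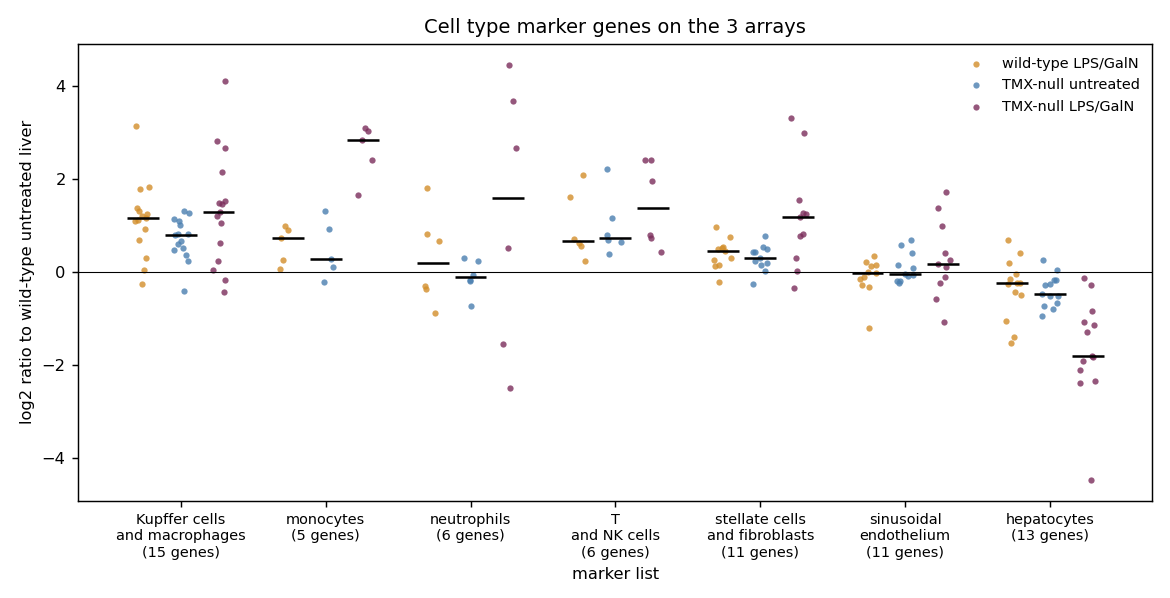
Cell type marker genes on the 3 arrays, with each point a gene and its log2 ratio to untreated wild-type liver on the y axis. Black bars are list medians. The monocyte median was 0.73, 0.28 and 2.82 on the wild-type LPS/GalN, TMX-null untreated and TMX-null LPS/GalN array, and the hepatocyte median -0.25, -0.48 and -1.82.

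Treated against untreated TMX-null liver gave the response to LPS/GalN without TMX, free of the reference if its RNA was the same preparation on both arrays. At 2-fold, 1158 genes were higher and 1230 lower. Ly6d (5.70), Ccl2 (5.27), the oestrogen sulfotransferase gene Sult1e1 (4.88), S100a4 (4.73), S100a9 (4.63), Pdlim7 (4.58), Tnfrsf12a (4.51) and Cdkn1a (4.13) were the highest. Upp2 (-5.99), Inmt (-4.54), Dbp (-4.52), Thrsp (-4.47), the ornithine aminotransferase gene Oat (-4.46), Hsd3b6, Hsd3b3 and Car3 (each -4.37) were the lowest. The interferon list had its median at 1.34 here, with 11 of 19 genes higher, and monocyte markers stood at 1.88. Neutrophil markers stood at 1.98, with 3 of 6 genes 2-fold higher and 2 lower. Cytochrome P450 genes stood at -2.18, with 29 of 33 lower, urea cycle and amino acid genes at -2.19, bile acid genes at -2.03, and hepatocyte markers beside them at -1.10. Cholesterol synthesis stood at -1.66, from Sc5d (-2.83) to Lss (0.29). Macrophage markers lay inside the random range at 0.40, although Marco stood at 3.00. The clock list stood at 0.65, but its mean was -0.07, with 2 of 15 genes 2-fold higher and 5 lower. Arntl, a core activator, stood at 3.48 and its output genes Dbp at -4.52 and Tef at -2.42.

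After LPS/GalN, TMX-null liver differed from wild-type liver in 2062 genes, 981 higher and 1081 lower. Ccl2 (5.82), Sult1e1 (5.29), Ly6d (4.87), S100a4 (4.74), Tnfrsf12a (4.16), Pdlim7 (4.06), the potassium channel subunit gene Kcne4 (3.70) and the interferon-induced chemokine gene Cxcl10 (3.50) were the highest. Thrsp (-5.49), Upp2 (-5.46), Hsd3b3 (-5.30), Car3 (-5.21), Hsd3b4 (-5.17), Hsd3b6 (-5.13), Hsd3b1 (-4.69) and Inmt (-4.63) were the lowest. Interferon response genes stood at 1.26, with 12 of 19 higher. Monocyte markers stood at 2.09, neutrophil markers at 1.76 (3 of 6 higher and 2 lower), extracellular matrix genes at 1.19 and ribosome biogenesis at 1.01. Stellate cell markers (0.94) and cholangiocyte and progenitor markers (0.98) lay high beside the matrix genes. Cytochrome P450 genes stood at -1.89 (27 of 33 lower), bile acid genes at -1.91, cholesterol synthesis at -2.00, urea cycle and amino acid genes at -2.02 (20 of 21) and coagulation and complement at -1.30, beside hepatocyte markers at -0.95. Male-biased genes stood at -2.75, with Hsd3b5 at -4.15. Macrophage markers did not stand apart, at 0.12. The acute phase list stood at -0.87, with Saa3 and Saa4 each at -3.22 and Hamp at 3.11, though Hamp2 stood at 0.58.

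The difference of the responses in the 2 genotypes was at least 2-fold for 1000 genes in one direction and 1176 in the other, and the SD of a single probe was 0.65 log2 for it, which leaves out differences between mice. The response in TMX-null liver exceeded that in wild type most for Sult1e1 (6.10), Ccl2 (5.28), Pdlim7 (5.20), Ly6d (5.18), Hamp (4.38, beside 1.59 for Hamp2) and S100a4 (4.02). It lay lowest for Rgs16 (-5.24), Upp2 (-5.12), Hsd3b4 (-4.94), Hsd3b3 (-4.89), Hsd3b6 (-4.78) and Car3 (-4.71). By list, the interferon median was 1.47 and the monocyte median 1.82. Those of cytochrome P450 genes (-1.84), bile acid genes (-1.85), urea cycle and amino acid genes (-1.83), cholesterol synthesis (-1.46) and male-biased genes (-2.69) were negative. So was that of the unfolded protein response (-0.51, with Herpud1 at -2.72). In treated TMX-null liver against the reference, however, this last list lay inside the random range (-0.28, percentile 10.2). It lay above the range on the 2 arrays subtracted here, at 0.26 in treated wild-type and 0.21 in untreated TMX-null liver. Tmx1 stood at -1.51, a value whose sign turned to 1.41 when arrays were scaled to the same spread. Under that scaling, 11 list medians lay outside the random range in place of 21.

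Across genes, which are not independent replicates, the wild-type response and the TMX-null response correlated with Pearson's r = 0.37 (Spearman's rho = 0.36), and these share no array. Of the genes 2-fold different in treated wild-type liver, 78.2% had the same sign in the TMX-null response. In both responses 132 genes were 2-fold higher, where independent lists would share 32.4, and 63 lower, where they would share 21.5, while 27 lay on opposite sides. Among pairs of arrays, which share the reference, r was 0.47 for wild-type LPS/GalN with untreated TMX-null, 0.52 for both treated livers and 0.40 for both TMX-null livers. Simulated unchanged livers against a shared reference gave 0.50, or 0.33 with noise added to each array, so part of these correlations may come from the reference. Both values follow from the settings, in which reference, livers and noise had the same spread, and were not estimated from these arrays. Over 81 genes with 2 probes, r between probes of the same gene was 0.31 on the wild-type LPS/GalN array. It was 0.17 on the untreated and 0.44 on the treated TMX-null array. Effects of single probes, such as dye effects common to all arrays, may therefore contribute to the correlations between arrays as well. The covariances of these array pairs were 0.092, 0.260 and 0.166, and a shared reference alone gave 0.080 in simulation at the spread of the untreated TMX-null array. That value follows from its setting too, in which reference and liver had equal parts in that array's variance. It does not measure what the real reference contributed.

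**Figure D3:**
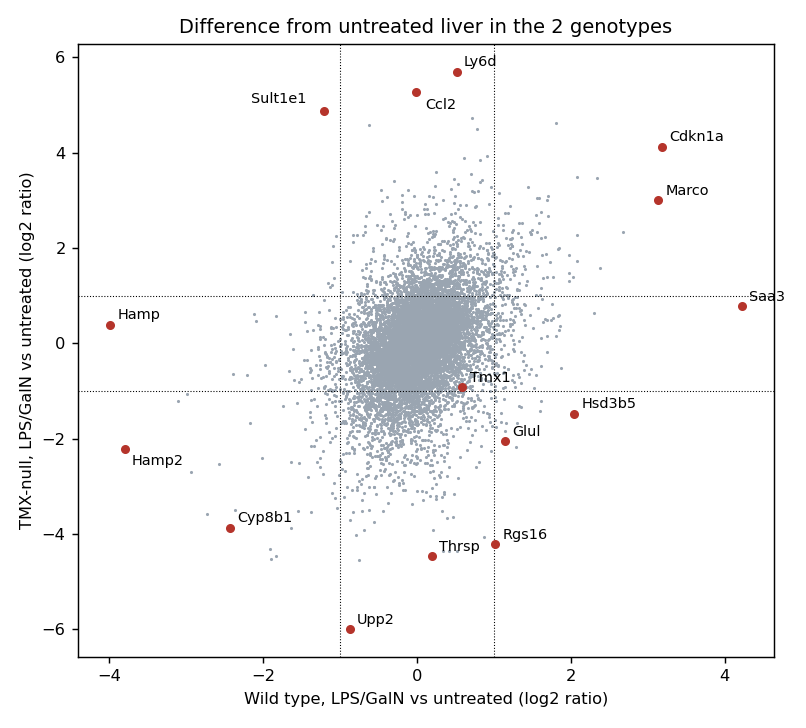
Log2 ratio of LPS/GalN over untreated liver in wild type (x axis) and in TMX-null liver (y axis) for 10179 genes, with dotted lines at 2-fold and some named genes in red. Cdkn1a stood at 3.18 and 4.13, Saa3 at 4.22 and 0.78, and Sult1e1 at -1.21 and 4.88.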

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

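All tests of explanations in this part were chosen after the results were seen.

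For 8 named genes the difference after LPS/GalN was at least 2-fold in both genotypes and in opposite directions. With 1 array per group, none of these differences was tested. The response in TMX-null minus that in wild type was 6.10 for Sult1e1, an oestrogen sulfotransferase (-1.21 in wild type and 4.88 in TMX-null), and 2.37 for Rrp9 (-1.35 and 1.02). It was -5.24 for Rgs16, a regulator of G protein signalling (1.02 and -4.22), -3.53 for Hsd3b5, a male-biased steroid enzyme (2.04 and -1.48), -3.21 for Glul, glutamine synthetase (1.15 and -2.06), -3.02 for Nkg7 (1.60 and -1.42), -2.70 for Cyp2d10 (1.36 and -1.35) and -2.29 for Sema7a (1.13 and -1.16). Nkg7, Sema7a, Rgs16 and Glul were also 2-fold higher in untreated TMX-null liver, at 2.21, 1.89, 1.43 and 1.18. Their lower response in TMX-null liver was measured from these high values, and against the reference Glul stood at -0.88 in treated TMX-null liver. Over all genes 27 behaved in this way, 18 higher in wild type and lower in TMX-null and 9 the reverse.

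In data outside the main measurement, counts were higher in the treated livers than in untreated TMX-null liver. Among named genes without a value on every array, 555 of 2159 (25.7%) were at least 2-fold higher and 24 lower in treated wild-type liver, and 535 of 1576 (33.9%) higher and 26 lower in treated TMX-null liver, against 382 of 1172 (32.6%) higher and 5 lower in untreated TMX-null liver. Which cells are blank goes with the ratio itself, and the share in treated wild-type liver was below that in untreated TMX-null liver, so these counts are no evidence of a response. Among 3401 unnamed features measured on all 3 arrays, 174 differed at least 2-fold in treated wild-type liver and 881 in treated TMX-null liver, against 92 in untreated TMX-null liver.

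The first pattern weighed was the larger number of 2-fold genes in treated TMX-null liver (2727) than in treated wild-type liver (463). Random noise alone on that array is argued against by 26 of the 40 lists lying outside the random range. Such noise would leave 2 or so. Noise added to real differences would leave lists outside too while raising the count, so it stays open as a part of the cause. A lower share of hepatocyte RNA raises markers of all other cells alike. Yet the monocyte median (5 genes) exceeded the sinusoidal endothelium median (11 genes) by 2.65, outside the range of random pairs of lists (-1.15 to 1.13). This argues against it as the only source of the high monocyte markers, if endothelial RNA was not lost as well. The lower genes were not tested for it, so it stays open for them. More monocytes cannot be told apart from higher expression of these 5 genes in other cells. A stretched scale of that array stays open. With all arrays at equal spread the counts were 1090 and 1029, which real changes in many genes would give too, and the SD of a single probe was also larger there, at 0.76 against 0.42. With 1 array per group, genotype cannot be told apart from a difference in severity or timing of injury between mice. A stronger injury without TMX is a hypothesis beside these.

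The second pattern was the height of macrophage markers on all 3 arrays (1.16, 0.79 and 1.29). In the difference between treated wild-type and untreated TMX-null liver the median was 0.37, outside the random range of -0.23 to 0.24. Reference and dyes cancel there if the reference RNA was the same preparation, and they then do not account for that excess. The labels do not state whether it was. In treated against untreated TMX-null liver (0.40) and between treated livers (0.12) the list lay inside the range. A part common to all arrays may come from a reference liver low in macrophage RNA or from the dyes. The 0.79 in untreated TMX-null liver may come from these or from the deletion. They cannot be told apart because every array had untreated wild-type liver as the reference, in the same dye.

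The third pattern was the low cholesterol synthesis list in untreated TMX-null liver (-0.63). A reference or dye effect would appear in treated wild-type liver too, but the difference between those arrays was -0.60 (random range -0.22 to 0.21). This reading assumes the same reference RNA on both arrays, and that LPS/GalN did not raise the list by as much. A lower hepatocyte share is argued against as the whole cause by the bile acid list, from which cholesterol synthesis differed by -0.57 (random range -0.28 to 0.28), with 20 of 20 bile acid genes above its median, and by cytochrome P450 genes (-0.51, random range -0.25 to 0.26). As part of the cause it stays open, since hepatocyte markers (-0.48) and secreted liver proteins (-0.34) lay low too, and cholesterol synthesis differed from the former by -0.16, inside the random range of -0.32 to 0.31. Time of day or feeding stays open, since the labels give neither. The clock list lay at percentile 0.64, with 11 of 15 genes below 0, but its members peak at different times of day. Its median therefore cannot decide on time of day, and the activator Arntl (-0.62) and its output gene Dbp (-0.73) lay low together. Lipogenesis lay low as well (-0.41), while the gluconeogenesis and fasting list (0.08) and PPARA targets (0.10) had members on both sides and decide nothing. An effect of the deletion is a further hypothesis that 1 array cannot separate from these.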

How the results depend on the processing

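Replacement of the reference by the untreated TMX-null array was the only setting chosen after the data were seen, and it gave 414 genes for treated wild-type liver. No paired analysis was possible because each group has 1 array. For treated wild-type liver, untreated TMX-null liver, treated TMX-null liver, treated against untreated TMX-null liver, treated TMX-null against treated wild-type liver and the difference of responses, in this order, a 1.5-fold threshold gave 1828, 1276, 5142, 4761, 4296 and 4471 genes and a 3-fold threshold 78, 23, 1134, 921, 768 and 772. A natural logarithm gave 1253, 834, 4398, 4004, 3618 and 3742. Arrays scaled to the same spread gave 1029, 1016, 1090, 1395 and 1001 for the first 5, and the difference of responses stayed within 1.5 times. Genes measured on the comparison's own arrays gave 998 and 640 for the first 2, with 76.7% and 83.8% of them higher in place of 61.6% and 68.0%. In untreated TMX-null liver the share was 57.4% with equal spread and 58.0% with a natural logarithm. The thresholds and the logarithm act by construction, and the other causes were not tested. Centring, the choice of probes and unnamed rows kept every count within 1.5 times. Lists outside the random range numbered 19 in place of 10 in treated wild-type liver with list means, and 11 in place of 21 for the difference of responses with equal spread. Turning the sign made Tmx1 2.96 in untreated TMX-null liver. Its difference of responses, -1.51, became 1.41 with equal spread, and no other named gene among the ranks reversed. Of list medians of at least 2-fold, 0 changed sign under the 7 settings run for them, which leave out turning the sign. Over all 240 list medians, 17 changed sign with list means, 16 with equal spread and 8 with the comparison's own arrays. Without centring 4 did, and with centring on the trimmed mean 1 did. Over settings, r kept to 0.40 to 0.54, 0.46 to 0.60, 0.35 to 0.49 and 0.32 to 0.44 for the 3 array pairs and the 2 responses. Signal over background is not in the table, so its limits are unknown.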

Other observations

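The genes of the next paragraph, the clock genes and the count of neighbours were chosen after the values were seen.

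Genes without a value on every array stayed outside the comparisons, and several of the largest ratios were among them. In treated TMX-null liver Chil3, a chitinase-like protein of macrophages, stood at 8.11 with no value on the other arrays. Ccl7, a monocyte chemokine, stood at 5.96 there and at 2.52 in treated wild-type liver, and Mmp12, the macrophage elastase, at 5.12 and 2.28. Ccl12 (3.71), Cxcl2 (3.77) and the AP-1 gene Fosl1 (4.78) had a value in treated TMX-null liver alone, and Ccl4 stood at 3.72 there and at 1.59 in untreated TMX-null liver. In treated wild-type liver Bcl6, a transcriptional repressor, stood at 2.87 and at 0.65 in untreated TMX-null liver. The rule behind blank cells is not known, so a blank is no evidence of absence, and 76.1%, 78.3% and 76.3% of the values of such genes lay above 0 on the 3 arrays.

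Uridine and iron genes had members on both sides. Galactose and uridine genes had a median of -0.28 in treated TMX-null liver, inside the random range, but Upp2 stood at -6.33 and Dpyd at -3.26 while Cad, which starts pyrimidine synthesis, stood at 2.46 and Upp1, the other uridine phosphorylase, at 1.72. In treated wild-type liver Upp2 stood at -0.88, Dpyd at -0.96 and Cad at 0.49. Hamp stood at -3.99 in treated wild-type liver and -0.88 in treated TMX-null liver, but its copy Hamp2 at -3.80 and -3.23, so the contrast rests on a single probe. Id1, a target of the BMP signal that controls Hamp, stood at 2.83 in treated TMX-null liver. Tfrc, the transferrin receptor, stood at 1.97 and 1.57. PPARA targets had medians of -0.19, 0.10 and -0.13 on the 3 arrays, with Acot3 at -2.99 in treated wild-type liver and Plin2 at 3.07 in treated TMX-null liver.

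The clock list lay inside the random range on both treated arrays (-0.13 in wild-type and 0.19 in TMX-null liver), but 3 and 7 of its 15 genes differed at least 2-fold there, and none in untreated TMX-null liver. Arntl stood at 2.07 in treated wild-type and 2.87 in treated TMX-null liver Dbp at -1.90 and -5.25 and Ciart at -1.46 and -1.77, while in untreated TMX-null liver they stood at -0.62, -0.73 and 0.04. The time of day of sampling is not given in the sources used here.

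Of the protein-coding genes within 20 places of Tmx1 on either side, in the gene order of assembly GRCm38.p6, 28 had a value in untreated TMX-null liver and 3 differed at least 2-fold (10.7%), against 5.78% of all 11351 genes with a value there, centred as in the main measurement and with all probes valued on that array averaged. These were the adjacent Trim9 (2.88), 2700049A03Rik (-1.34) and Ccdc175 (-1.10). Trim9 stood at 1.54 in treated TMX-null liver and had no value in treated wild-type liver.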
